A study of Homo sapiens with 3 samples.

How the data were processed

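The series measured gene expression and chromatin accessibility in the same cells with the 10x Genomics Multiome assay in NCI-H226, a human mesothelioma cell line with loss of NF2, and in CL3, a clone of it that had grown resistant to the TEAD inhibitor GNE7883. Per the labels' protocols, resistance was selected with rising doses from 0.25 to 3 µM in steps of 0.1 to 0.5 µM. Parental and CL3 cells with GNE7883 or with DMSO were marked with hashtag antibodies, pooled, permeabilised and run together, and 3 libraries were made (expression, accessibility and hashtags), with raw reads per cell of about 20, 30 and 2 in units of 1000.

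The deposited matrix holds whole-number counts per feature and barcode, per the file headers, which also name Cell Ranger ARC 2.0.0. Entries for genes are unique molecular identifiers (UMIs) and entries for peaks are transposition counts. Of the peak entries, 87.9% were even, so intervals on peaks treat every 2 counts as 1 event. The processing notes of the submitters name Cell Ranger 2.0.0, Cell Ranger ARC 2.0.0, ArchR 1.0.3, MACS2 and GRCh38.p10 without giving their roles, and how the peaks were called is not given in the sources used here. The counts carry no normalisation and the barcodes had not been filtered to cells. The matrix holds 36601 genes and 215590 peaks in 651860 barcodes that share 1 channel suffix. It names no hashtag among its features, and the accompanying list gives only the names and sequences of 4 hashtags. No barcode could therefore be assigned to a line or a treatment. All cells form 1 pooled sample. No condition was compared, no cluster was read as a condition or a line, and no p-value was computed, since cells are not replicates.

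A barcode was kept as a cell with at least 1000 UMIs, at least 1000 peak counts and at most 20% of UMIs from mitochondrial genes. Of 11130 barcodes past both count minimums, 2217 exceeded the mitochondrial limit and 8913 cells remained. Doublets marked by 2 hashtags could not be removed. Scrublet, as implemented in scanpy, marked 0 of the 8913 cells at its automatic threshold, so it has not worked here, and doublets remain among the cells. An alternative left out the 8% of cells with the highest Scrublet scores.

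Cells were clustered separately on each modality. For chromatin, counts in peaks found in at least 20 cells were weighted by term frequency and inverse document frequency and reduced to 30 components by singular value decomposition, without components correlated over 0.75 with depth. For expression, 2000 highly variable genes were reduced to 30 principal components after scaling each cell to 10000 counts. Both used 15 neighbours, Leiden resolution 0.5 and seed 0. The neighbour graph was weighted by the Jaccard overlap of shared neighbours. That weighting was adopted after the data were seen, because partitions from a fuzzy-weighted graph moved with rounding error, and several such partitions and embeddings had been looked at by then. Clusters are numbered by size and those of at least 100 cells were compared. A cluster would have taken a cell-type name with 3 markers at least 2-fold higher. None reached this.

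UMIs were summed over the cells of a cluster and over the cells compared with it, scaled to the same total (CPM), and divided. Ratios carry exact conditional binomial 95% intervals and shares of cells carry exact Clopper-Pearson 95% intervals. These intervals cover counting error only and were not adjusted for the number of genes or peaks compared. A gene was compared with at least 100 UMIs over both sums and at least 20 CPM in the higher one. A gene low over all cells can thus enter a comparison through the cluster where it is high. The random lists described below drew on genes that met the same floor. The comparison between the 2 largest chromatin clusters and the 26 gene lists were fixed before the data were examined, as were the cell filter, the named-gene rule, most alternatives and the cluster settings other than the graph weights. The lists are YAP/TEAD targets, MAPK output, AP-1, Hippo pathway and TEAD cofactors, EGFR family, other receptor tyrosine kinases, S phase, G2/M phase, BCL2 family, mesenchymal transition, integrins and matrix, interferon response, NF-kB and cytokines, TGF-beta and BMP response, cholesterol synthesis, unfolded protein and ATF4 response, hypoxia and glycolysis, p53 targets, NRF2 targets, drug efflux pumps, mesothelial, epithelial and squamous, fibroblast and smooth muscle, immune and endothelial markers, and housekeeping genes. A member counts as higher or lower at 1.5-fold with an interval that excludes 1. A list is given as the median log2 ratio of its compared members, where at least 3 were compared, with the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins, and with a 95% interval from order statistics. Random members were drawn independently, so the percentiles ignore co-expression among list members, and the interval treats members as independent too. The percentiles were not adjusted for the number of lists and comparisons and are no p-values.

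The rule for named genes took, among genes at least 2-fold apart, up to 10 with the largest ratio each way without clone names, mitochondrial or ribosomal protein genes, then up to 4 members of each list with the largest ratio, and 14 fixed genes. It was written for cluster 1 against cluster 2 and was extended to each cluster against all other cells after the data were seen. The text names part of what it allows. MX1 in cluster 2, NUF2, TOP2A, MKI67 and MCM6 in cluster 5, and KRT7 over all cells lie outside it and were chosen after their values were seen. The rule for peaks took the 5 with the largest ratio each way with at least 100 counts. Promoter accessibility was the sum over peaks within 2 kb of the interval that the feature list gives for a gene, from its start to its end, which 24839 of the 36601 genes had. Where that interval is wide the sum can take in peaks away from a promoter. Levels of lists per cell were correlated by rank after thinning each cell to 1000 UMIs and set against 1000 pairs of matched random lists.

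Chromosome-wide shifts were looked for after a first exploration of the data. The median log2 ratio over the peaks, and over the genes, of each of 23 chromosomes was taken relative to the median over all of them, for features with at least 200 counts and with a pseudocount of 1. Its 95% interval comes from order statistics, as for the list medians. A chromosome was called where both shifts lay past 0.15 in the same direction with intervals on that side. For comparisons at matched depth, cells were put into 10 bins of UMIs by 10 bins of peak counts, and equal numbers of cells of the cluster and of other cells were drawn from each bin, 20 times. The steps were tested on simulated data. For cluster 2 against cluster 1 over 6768 genes, 31 of 33 genes simulated at 1.5-fold, 35 of 35 at 2-fold, 44 of 44 at 3-fold and 36 of 36 at 4-fold were recovered, with an interval on the simulated side of 1. Of 6620 unchanged genes 0 were called at 2-fold, a stricter rule, and the intervals of 6307 included 1. For expression cluster 5, 1.5-fold gains on chromosomes 8 and 19, a true log2 of 0.585, were both called, at accessibility shifts of 0.55 and 0.56, with 0 other chromosomes called. Both simulations drew counts from 1 shared profile without variation between cells. They test the steps under counting error only and say little about false calls in the real data. The gene simulation used the 2 largest chromatin clusters, so it gives no rate of false calls for smaller clusters.

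The alternatives changed the cell filter, mitochondrial limit, scaling (TMM factors of edgeR and median-of-ratios factors of DESeq2), minimum UMIs, thinning, doublet treatment, resolution, components, neighbours, seed, graph weights, peak minimum, peak scaling, list statistic and the modality clustered. Under another clustering a cluster counts as found again only where it and its partner were each other's best match with a Jaccard overlap of at least 0.1. This rule was set after a first run. Comparisons between conditions, hashtag demultiplexing, the drug response and motif shares, which need a genome sequence, were left out. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.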

Results

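The data are 3 libraries of 1 pool of cells, 1 each for gene expression, chromatin accessibility and hashtags. The pool mixed parental NCI-H226 mesothelioma cells and their GNE7883-resistant clone CL3, each with the TEAD inhibitor GNE7883 or with DMSO. The study asks how resistant cells differ from sensitive ones and how each responds to the drug. Because the matrix used here names no hashtag, the cells form 1 sample without replicates, and the comparisons here are between groups of cells found in the data. They cannot be read as drug or line effects. The matrix holds 54494965 UMIs and 117898281 peak counts, of which 30.4% and 41.1% lie in the 8913 cells kept. A cell had a median of 1524 UMIs (1000 to 13064) from 912 genes and 4034 peak counts (1001 to 59374) in 2097 peaks, with 13.9% mitochondrial UMIs. NF2, the Hippo pathway tumour suppressor that this line lacks, had 4 UMIs in all cells, or 0.241 CPM (95% interval 0.0657 to 0.617). Of the TEAD factors and their cofactors, TEAD1 stood at 388 CPM, YAP1 at 138 CPM, VGLL3 at 131 CPM, WWTR1 at 49.0 CPM and TEAD4 at 39.4 CPM. The mesothelial markers summed to 10539 CPM, and to 12961 CPM in free RNA. Most of the 10539 CPM came from the keratins KRT18 (4153 CPM), KRT8 (2517 CPM) and KRT19 (1742 CPM). Of the other members CALB2 stood highest, at 771 CPM, with MSLN at 79.0 CPM and WT1 at 68.4 CPM. The epithelial and squamous markers summed to 1845 CPM (2412 CPM in free RNA), of which the keratin KRT7 alone had 1826 CPM, and of these 15 genes no other reached 20 CPM and 4 had no UMI. The 12 immune markers summed to 9.10 CPM (7.58 CPM in free RNA), with 5 of them at 0 UMIs, and the endothelial markers to 58.2 CPM (60.65 CPM in free RNA).

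Chromatin accessibility divided the cells into 6 clusters of more than 100 cells, and 1 cell stood alone. Cluster 1 held 3701 cells (41.5%, 95% interval 40.5 to 42.6), cluster 2 held 1849 (20.7%, 19.9 to 21.6), cluster 3 held 1269 (14.2%), cluster 4 held 1186 (13.3%), cluster 5 held 786 (8.82%) and cluster 6 held 121 (1.36%). Cells of cluster 1 were the shallowest, with medians of 1305 UMIs and 2254 peak counts. Clusters 2 to 5 had medians of 1674 to 1914 UMIs and 5537 to 6422 peak counts. Since peaks alone defined these clusters, gene expression was not used to draw them. The 2 readings come from the same cells, and depth can affect both.

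In the comparison of cluster 1 with cluster 2, the pair of largest chromatin clusters, interferon response and MAPK output genes had the largest shares of members past 1.5-fold (8 of 17 and 4 of 9). Of 6934 genes compared, 25 were at least 2-fold higher in cluster 1 and 21 at least 2-fold lower. Against all other cells 0 of 6711 genes were at least 2-fold higher or lower in cluster 1, so higher and lower here are relative to cluster 2 only. PTPRQ and CHI3L1, for example, were lower in cluster 2 than in all other cells. Higher in cluster 1 were CHI3L1, a secreted chitinase-like glycoprotein (3.44-fold, 95% interval 2.65 to 4.52), PTPRQ, a receptor-type phosphatase (3.21-fold, 2.83 to 3.64), PPP2R2B, a regulatory subunit of the phosphatase PP2A (3.12-fold), CLSTN2 (2.96-fold), DANT2 (2.80-fold), the acute-phase protein SAA1 (2.56-fold, 2.37 to 2.77), LCN2 (2.52-fold), and ISM2, PLLP and surfactant protein SFTPD (each at a log2 ratio of 1.32). Lower in cluster 1 were IFI44L (2.88-fold lower, 1.94 to 4.35), IL1RAPL1 (2.51-fold), the metalloprotease ADAMTS6 (2.48-fold), the chromatin architectural protein HMGA2 (2.30-fold, 2.11 to 2.51), SAMD3 (2.26-fold), the ERBB3 ligand NRG1 (2.24-fold, 1.85 to 2.73), the ERK phosphatase DUSP4 (2.24-fold, 1.59 to 3.18), the peptidase MME (2.23-fold), GNB4 and the transcription factor RUNX2 (each 2.13-fold).

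Of the 9 MAPK output genes compared, 4 were at least 1.5-fold lower in cluster 1 and 0 higher, with a median log2 ratio of -0.50 (-0.86 to -0.25), at the 0.01 percentile of matched random lists. Besides DUSP4 they were SPRED2 (1.81-fold lower), ETV5 (1.78-fold) and PHLDA1 (1.64-fold). DUSP4, SPRED2 and ETV5, and IFI44L named above, lie under 20 CPM over all cells and met the floor in cluster 2. Interferon response genes had 8 of 17 members lower and a median of -0.53, at the 0 percentile, with IFIT3 at 1.87-fold and OAS3 at 2.11-fold lower. YAP/TEAD targets had 2 of 17 lower and a median of -0.18 (-0.35 to 0.017), among them the kinase receptor AXL (1.52-fold lower) and CCN2 (1.54-fold), while CCN1 stood at a log2 ratio of -0.14 and AMOTL2 at -0.29. The Hippo pathway genes had 0 of 12 past 1.5-fold, with YAP1 at -0.18, TEAD1 at -0.057, TEAD4 at -0.046 and WWTR1 at 0.12, and VGLL3 was 1.46-fold higher. NF-kB and cytokine genes had 3 of 11 higher, ICAM1 (1.58-fold), CCL20 (1.59-fold) and CXCL8 (1.57-fold), and 1 lower, with a median of 0.25 at the 99.98 percentile. ANKRD1, DUSP6 and SPRY4 were under the 20 CPM floor in both clusters.

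The other lists had few members past 1.5-fold, but the medians of several lay far out among matched random lists: G2/M phase at the 0 percentile, mesenchymal genes at 0.04, S phase at 0.44, cholesterol synthesis at 99.5 and mesothelial markers at 99.3. Since random members were drawn independently, a small shift shared by the members of a list can place it far out. Median log2 ratios were -0.21 for AP-1, with FOSL1 1.77-fold lower as its 1 member of 7, -0.36 for the EGFR family (1 of 3 lower), -0.16 for other receptor tyrosine kinases (1 of 10 higher), -0.22 for S phase (2 of 25 lower), -0.24 for G2/M phase (1 of 47 lower) and -0.23 for the BCL2 family (0 of 6). They were -0.32 for mesenchymal genes (1 of 13 lower), -0.11 for integrins and matrix (1 of 14 lower), 0.022 for TGF-beta and BMP genes (1 of 9 higher, 2 lower), 0.10 for cholesterol synthesis (0 of 18), -0.17 for the unfolded protein response (2 of 12 lower) and -0.13 for hypoxia genes (1 of 11 lower). They were -0.21 for p53 targets (1 of 12 lower), 0.040 for NRF2 targets (0 of 5), -0.15 for efflux pumps (2 of 5 lower), 0.17 for mesothelial markers (1 of 12 higher), -0.065 for fibroblast markers (0 of 4) and -0.033 for housekeeping genes (0 of 11). Of epithelial and endothelial markers 1 each was compared and of immune markers 0, too few for a median. The count of 25 higher and 21 lower became 29 and 12 under TMM and under median-of-ratios scaling, and the total of 46 lay between 0, at Leiden resolution 1.0, and 348, at a minimum of 10 UMIs. Among cells with at most 10% mitochondrial UMIs, PTPRQ, PPP2R2B, DANT2, HMGA2, SAMD3, DUSP4, RUNX2, ETV5, IFIT3, CXCL8 and CCL20 turned to the opposite side, as did the S phase and cholesterol synthesis medians, and the MAPK median was -0.12. The cells were clustered again there, and the cluster matched to cluster 2 shared a Jaccard overlap of 0.22 with it. The efflux pump median turned positive with at least 2000 UMIs and peak counts.

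Against all other cells, cluster 2 had 57 genes at least 2-fold higher and 45 lower of 6947. IFI44L was 4.10-fold higher (2.91 to 5.81), IL1RAPL1 3.72-fold, ADAMTS6 3.61-fold, HMGA2 3.49-fold (3.23 to 3.77), SAMD3 3.48-fold and INHBA, which encodes the activin A subunit, 2.49-fold (2.26 to 2.76). PTPRQ was 4.25-fold lower, CHI3L1 3.70-fold lower and ADGRL3, an adhesion receptor, 3.18-fold lower. Interferon response genes were higher in 13 of 17 and lower in 0, with a median log2 ratio of 0.81 (0.60 to 1.19) at the 100 percentile, including IFIT3 (2.31-fold), OAS3 (2.30-fold), IFI44 (2.29-fold) and MX1 (1.99-fold). MAPK output genes were higher in 4 of 9 and lower in 0, with a median of 0.47 (0.34 to 1.06) at the 99.9 percentile. The 4 were DUSP4 (2.73-fold, 2.05 to 3.65), the ETS factor ETV5 (2.08-fold), PHLDA1 (2.04-fold, 1.79 to 2.33) and SPRED2 (1.73-fold). DUSP4 (12.0 CPM over all cells), ETV5 (17.1 CPM) and SPRED2 (19.5 CPM) passed the 20 CPM floor only through cluster 2, so the share of 4 of 9 favours genes high there. With a minimum of 10 UMIs per member in place of the floor, the MAPK list median stayed within its interval. IFI44L (8.62 CPM over all cells) also passed the floor only through cluster 2. NRG1 was 2.25-fold higher (1.92 to 2.63) and the AP-1 member FOSL1 1.88-fold higher.

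YAP/TEAD targets had 2 of 17 members higher in cluster 2, CCN2 (1.72-fold) and NT5E (1.78-fold), with AXL at 1.49-fold, CCN1 at 1.10-fold and a list median of 0.13 (-0.058 to 0.46). The cofactor VGLL3 was 1.54-fold lower. Cell-cycle genes had positive medians, 0.37 for S phase (2 of 25 higher) and 0.33 for G2/M phase (4 of 47 higher), both at the 100 percentile, as had mesenchymal genes (0.39, 2 of 13 higher, 99.98 percentile). Hypoxia and glycolysis genes had 4 of 11 higher and 0 lower (97.9 percentile), p53 targets 2 of 12 higher and 0 lower (99.3 percentile), and the unfolded protein response 3 of 12 higher and 1 lower (85.9 percentile). NF-kB and cytokine genes had 3 of 11 lower and 1 higher (0.01 percentile), and mesothelial markers 3 of 12 lower (0.13 percentile). The cholesterol synthesis median of -0.14 (0 of 18 past 1.5-fold) lay at the 0.08 percentile. The split of 57 higher and 45 lower became 41 and 55 under TMM and under median-of-ratios scaling, and the total of 102 lay between 4, at most 10% mitochondrial UMIs, and 546, at a minimum of 10 UMIs. With at most 10% mitochondrial UMIs this comparison is the mirror image of that with cluster 1 and no separate result: HMGA2, SAMD3, PTPRQ, ADGRL3, DUSP4, ETV5, NT5E and IFIT3 turned to the opposite side, as did the S phase median (-0.13), and the MAPK median was 0.12. INHBA and CCN1 turned with at least 2000 UMIs and peak counts and in clusters drawn from expression without the list genes.

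**Figure D1:**
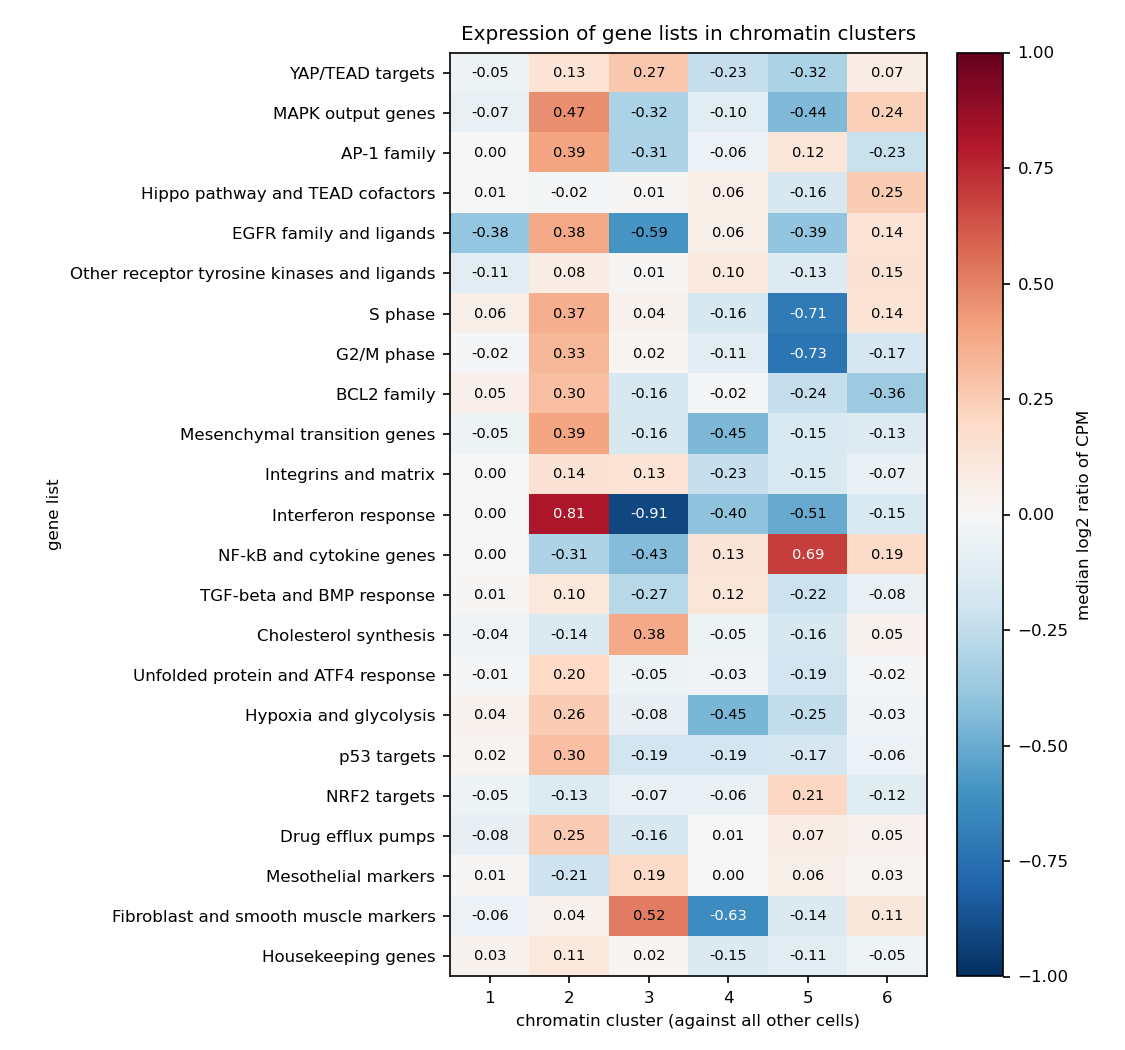
Median log2 ratio of CPM of each gene list (vertical axis) in chromatin clusters 1 to 6 (horizontal axis), each against all other cells, with red for higher and blue for lower. Interferon response genes ran from 0.81 in cluster 2 to -0.91 in cluster 3, and lists with fewer than 3 members compared are left out.

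Cluster 3 had 33 genes at least 2-fold higher and 41 lower of 6785. CLSTN2 was 3.16-fold higher (2.71 to 3.68), SYT17 3.07-fold, the vitamin D hydroxylase CYP24A1 2.86-fold (2.60 to 3.15), the transglutaminase TGM1 2.63-fold and the NRG1 receptor ERBB3 2.62-fold (2.20 to 3.10). YAP/TEAD targets were higher in 3 of 17 and lower in 0, with a median log2 ratio of 0.27 (-0.044 to 0.51) at the 99.99 percentile. The 3 were IGFBP3 (2.13-fold, 1.92 to 2.35), the secreted matrix protein CCDC80 (1.78-fold, 1.73 to 1.84) and tissue factor F3 (1.69-fold), while CCN1 was 1.43-fold and AXL 1.31-fold higher. MAPK output genes had 2 of 7 lower, PHLDA1 (1.54-fold lower) and SPRED2 (1.53-fold lower), and a median of -0.32 (-0.63 to -0.028). The gene for EGFR lay at a log2 ratio of -0.59 and NRG1 was 1.55-fold lower. The MAPK median was -0.69 in clusters drawn from expression without the list genes.

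Interferon response genes were lower in 13 of 16 members in cluster 3, with a median of -0.91 (-1.08 to -0.68) at the 0 percentile, including XAF1 (2.65-fold lower) and IFIT2 (2.29-fold lower), and MX2 was 3.39-fold lower. Cholesterol synthesis genes had a median of 0.38 (0.28 to 0.47) at the 100 percentile. Fibroblast markers had a median of 0.52 (1 of 4 higher), mesothelial markers of 0.19, with KRT5 2.31-fold higher as its 1 member of 13, and NF-kB genes of -0.43 (2 of 11 lower). IL1RAPL1 was 3.42-fold, HMGA2 3.17-fold and WWTR1, which encodes TAZ, 1.49-fold lower. The split of 33 higher and 41 lower became 37 and 34 under TMM and 37 and 35 under median-of-ratios scaling, and the total of 74 lay between 20, at Leiden resolution 1.0, and 412, at a minimum of 10 UMIs, and AXL turned to the opposite side at resolution 1.0.

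Cluster 4 had 58 genes at least 2-fold higher and 50 lower of 6888. The largest ratios were ADGRL3 (6.33-fold higher, 5.61 to 7.14), PPP2R2B (6.30-fold, 5.28 to 7.53), the integrin subunit ITGB8 (4.55-fold, 3.82 to 5.40) and PTPRQ (3.41-fold, 3.20 to 3.63). PHGDH, of serine synthesis, was 2.36-fold, the collagen receptor kinase DDR2 2.22-fold and WWTR1 1.49-fold higher. YAP/TEAD targets were lower in 5 of 16 and higher in 0, with a median of -0.23 (-0.59 to 0.030) at the 0.15 percentile: NT5E (2.97-fold lower, 2.03 to 4.52), AXL (1.77-fold), F3 (1.66-fold), IGFBP3 (1.51-fold) and CCN1 (log2 ratio -0.59). CCN2 and ANKRD1 were under the floor.

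Mesenchymal genes in cluster 4 had 3 of 12 lower and a median of -0.45, at the 0 percentile, with COL1A1 1.98-fold and TGFBI 1.91-fold lower, and fibroblast markers, which share COL1A1, 2 of 4. Hypoxia and glycolysis genes had 3 of 11 lower and a median of -0.45 (-1.09 to -0.21) at the 0.01 percentile, including the glucose transporter SLC2A1 (2.21-fold lower) and NDRG1 (2.13-fold lower). MAPK output genes had a median of -0.10, with PHLDA1 as the 1 of 6 lower (1.51-fold), and the interferon list -0.40 (3 of 16 lower, 0 percentile). IL1RAPL1 was 4.20-fold, CLSTN2 4.01-fold, HMGA2 2.97-fold and INHBA 2.77-fold lower. S phase and G2/M phase medians of -0.16 and -0.11 turned positive under several clusterings. The count of 108 lay between 14, in a neighbour graph without weights, and 525, at a minimum of 10 UMIs, and the MAPK median reached 0.29 with at least 2000 UMIs and peak counts.

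Cluster 5 had 71 genes at least 2-fold higher and 134 lower of 6833. NF-kB and cytokine genes were higher in 7 of 13 and lower in 0, with a median log2 ratio of 0.69 (0.46 to 1.23) at the 100 percentile, including the chemokines CXCL1 (3.73-fold, 2.63 to 5.22) and CXCL8 (2.52-fold) and the apoptosis inhibitor BIRC3 (2.35-fold). Higher too were the steroid hydroxylase CYP17A1 (6.36-fold, 4.86 to 8.30), SFTPD (4.69-fold, 4.15 to 5.29), ISM2 (4.56-fold), LCN2 (3.65-fold, 2.93 to 4.52), the epithelial ETS factor ELF3 (3.65-fold), CHI3L1 (3.56-fold) and hexokinase HK2 (2.11-fold). The AP-1 genes FOS (3.21-fold, 2.29 to 4.42), JUNB (1.91-fold) and FOSB (1.80-fold) were higher, 3 of 8 members, and 1 was lower. FOS (12.2 CPM over all cells) and FOSB (12.6 CPM) passed the floor only through cluster 5, as did CXCL1 (10.5 CPM). Over all cells 11 NF-kB and 6 AP-1 members reach 20 CPM, so the shares of 7 of 13 and 3 of 8 favour genes high in this cluster. G2/M genes were lower in 33 of 47 members, with a median of -0.73 (-0.82 to -0.64) at the 0 percentile, including the kinetochore motor CENPE (2.54-fold lower), the checkpoint kinase TTK (2.36-fold), NUF2 (2.19-fold), TOP2A (1.67-fold) and MKI67 (1.57-fold).

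S phase genes were lower in 15 of 22 members in cluster 5, with a median of -0.71 at the 0 percentile, including UHRF1 (2.08-fold lower), RRM2 (2.06-fold) and the replication helicase subunit MCM6 (2.04-fold). YAP/TEAD targets were lower in 4 of 16 and higher in 0, with a median of -0.32 (-0.63 to -0.20) at the 0.06 percentile, including F3 (3.48-fold lower, 2.26 to 5.65), GADD45A (1.88-fold) and AMOTL2 (1.65-fold), with CCN2 and ANKRD1 under the floor, and the median was -0.19 with at least 500 UMIs and peak counts. MAPK output genes had a median of -0.44 (-1.04 to 0.091) with 1 of 6 lower, PHLDA1 (2.05-fold). ADAMTS6 was 6.12-fold (3.62 to 11.2), INHBA 4.29-fold, the collagen receptor subunit ITGA2 3.30-fold, the efflux pump ABCG2 3.01-fold and NRG1 2.39-fold lower. Interferon response genes were lower in 7 of 16 and higher in 0, with a median of -0.51 (-0.68 to 0.00062) at the 0.04 percentile, including IFIT2 (2.76-fold lower). The split of 71 higher and 134 lower became 97 and 88 under TMM and 97 and 90 under median-of-ratios scaling, and the total of 205 lay between 45, with at least 500 UMIs and peak counts, and 640, at a minimum of 10 UMIs.

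**Figure D2:**
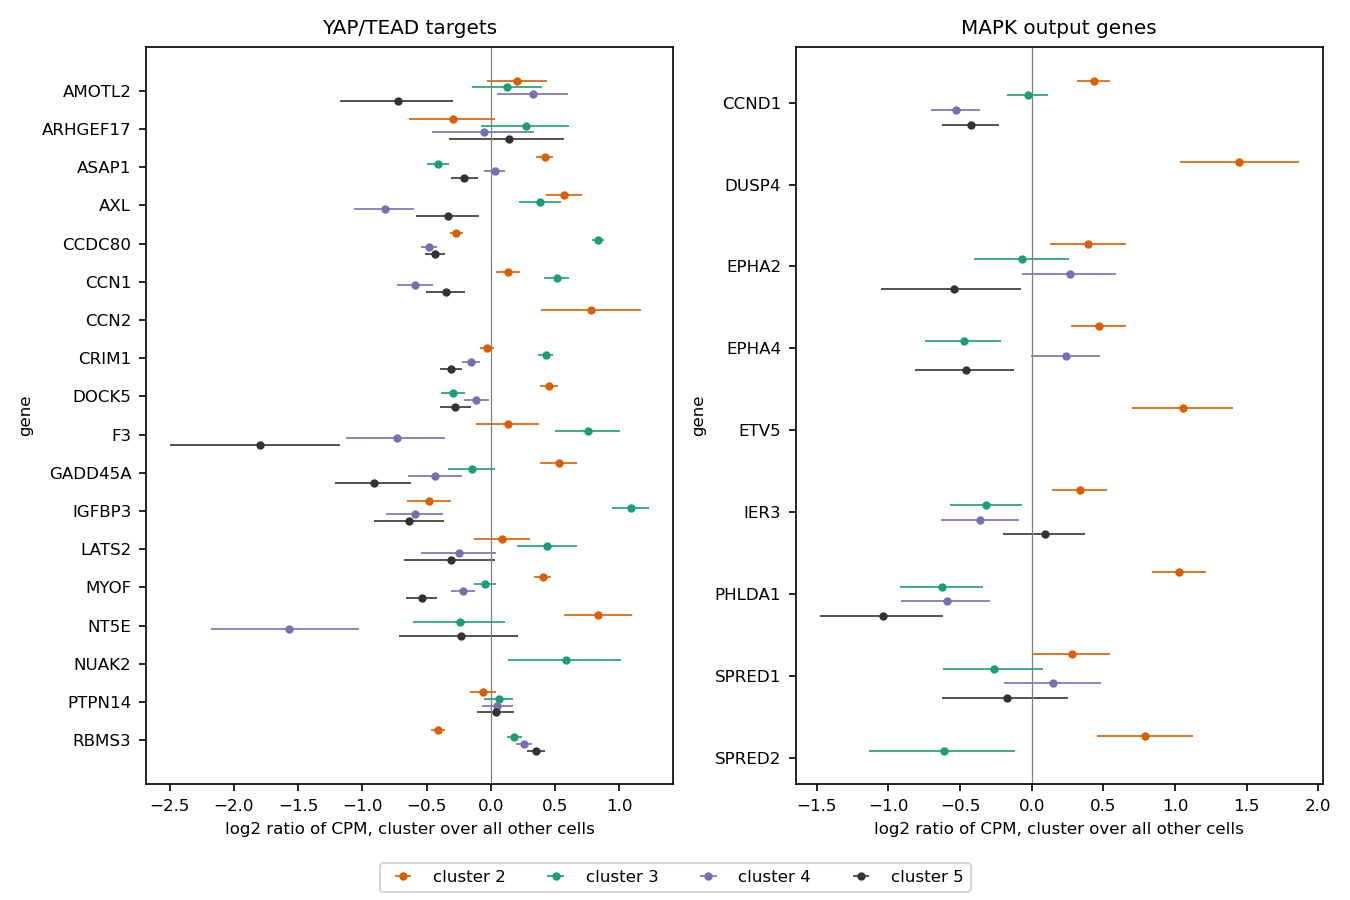
Log2 ratio of CPM (horizontal axis) of each YAP/TEAD target and MAPK output gene compared, in chromatin clusters 2 to 5 against all other cells, with 95% intervals of counting error. MAPK output genes lie highest in cluster 2 (median 0.47) and YAP/TEAD targets in cluster 3 (median 0.27), and members under 100 UMIs or 20 CPM in a cluster have no point.

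Cluster 1 against all other cells had 0 genes at least 2-fold higher and 0 lower of 6711. No list had a member past 1.5-fold, and the medians lay between -0.38 for the EGFR family, with 3 members compared, and 0.059 for S phase genes. Among matched random lists the EGFR family lay at the 0.005 percentile, other receptor tyrosine kinases (-0.11) at 1.21 and S phase at 98.6. The other lists lay between 4.22 and 87.3. At a minimum of 10 UMIs the count was 143.

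Cluster 6, of 121 cells and 221559 UMIs, had 86 genes at least 2-fold higher and 74 lower of 7120. The genes with the largest ratios had few UMIs in it. The intervals were not adjusted for the number of genes. How many calls counting error alone would give in so small a cluster was not determined, so these counts may hold many false calls. FAM104B was 4.42-fold higher (1.74 to 9.40) with 7 UMIs, UBR7 4.34-fold (1.56 to 9.79) with 6 and PIP5K1C 4.19-fold (2.06 to 7.66) with 11. UBR7 (6.51 CPM over all cells) passed the 20 CPM floor only through this cluster. Lower were STRN, with 1 UMI against 743 in all other cells (ratio 0.0994, 0.00251 to 0.556), SDHC, with 1 against 646 (0.114, 0.00289 to 0.639), SNX17, with 1 against 625 (0.118, 0.00299 to 0.661), and the housekeeping gene HPRT1, with 1 against 462 (0.160, 0.00404 to 0.895). YAP/TEAD targets had 1 of 17 higher and 0 lower, with a median log2 ratio of 0.074 (-0.21 to 0.25) at the 82.1 percentile. MAPK output genes had 0 of 7 higher and 1 lower, PHLDA1 (2.19-fold lower, 1.00 to 5.99, 6 UMIs), with a median of 0.24 (-1.13 to 0.71) at the 91.2 percentile. The NRF2 target HMOX1 was 2.81-fold higher (1.44 to 4.99), the 1 of 6 of its list. S phase genes had 2 of 24 higher, and no list had more than 2 members past 1.5-fold. The G2/M median of -0.17 (1 of 47 higher) lay at the 0.47 percentile and the Hippo median of 0.25 (0 of 12) at the 97.52 percentile, and the other medians between 5.905 and 88.9. The count of 160 was 72 at a minimum of 500 UMIs and 220 at a minimum of 10. The cluster was not found again under 5 of the 11 other clusterings.

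Whether YAP/TEAD target and MAPK output genes vary together from cell to cell was asked after thinning each of the 8913 cells to 1000 UMIs, which left a mean of 5.58 UMIs for the YAP/TEAD and 0.481 UMIs for the MAPK list. Their rank correlation was 0.017, inside the range of matched random pairs (-0.050 to 0.033). It lay between -0.014 and 0.065 within the 6 chromatin clusters. The correlation of MAPK output with interferon response genes was 0.040, at the 99.8 percentile of its own random pairs, and that of YAP/TEAD targets with interferon genes was -0.053, at the 2.1 percentile. These are descriptions of 1 pool, at a depth where most cells had no MAPK UMI to rank.

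Gene expression divided the same cells into 8 clusters. The 2 largest held 3806 and 2839 cells, with medians of 1472 and 1299 UMIs. The genes that define the others are given as their identity: IL1RAPL1, HMGA2 and SAMD3 for cluster 3 (633 cells), OSCAR, CYP24A1, CLSTN2 and ERBB3 for cluster 4 (483), PPP2R2B, ADGRL3 and ITGB8 for cluster 5 (395), LCN2, CXCL1, CYP17A1 and SAA1 for cluster 6 (331), IGFBP5, INHBA, ADAMTS6 and DUSP4 for cluster 7 (280), and the interferon-induced genes OASL, RSAD2, CCL5 and IFIT2 for cluster 8 (146). Most cells of expression clusters 3 to 7 fell into a single chromatin cluster each. Chromatin cluster 2 held 84.2% of expression cluster 3 and 71.4% of expression cluster 7, chromatin cluster 3 held 77.8% of expression cluster 4, chromatin cluster 4 held 88.6% of expression cluster 5 and chromatin cluster 5 held 63.1% of expression cluster 6. Expression cluster 8 was spread over chromatin clusters 1 (39.0%) and 2 (36.3%), and expression clusters 1 and 2 lay 50.3% and 52.2% in chromatin cluster 1. Over all cells the adjusted Rand index was 0.106, and it was 0.330 among cells with at least 2000 UMIs and peak counts and -0.0285 with at most 10% mitochondrial UMIs.

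**Figure D3:**
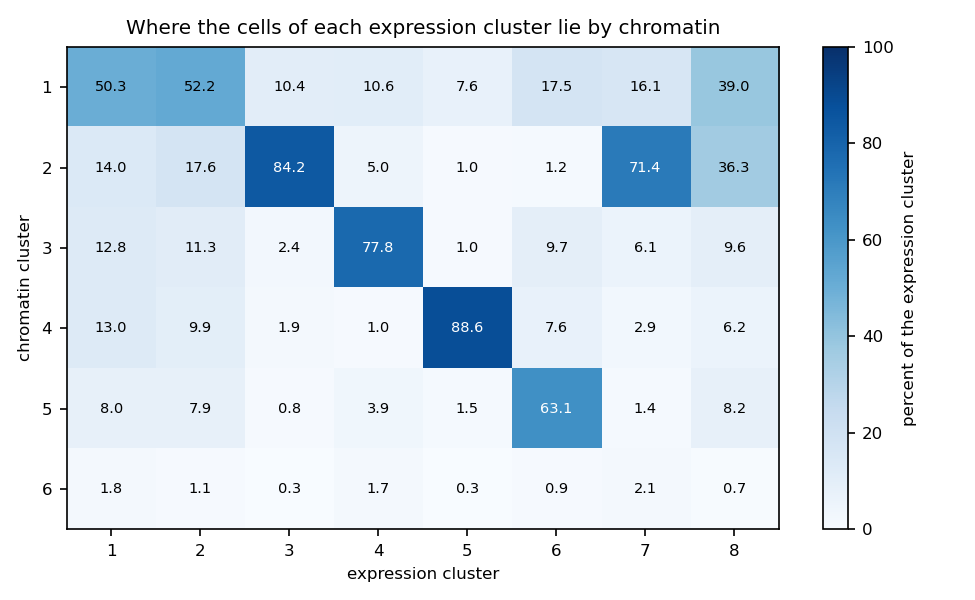
Percent of the cells of each expression cluster (horizontal axis) that lie in each chromatin cluster (vertical axis), with darker blue for a larger percent. Expression cluster 5 lies 88.6% in chromatin cluster 4 and expression cluster 8 is spread over chromatin clusters 1 and 2.

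Promoter accessibility was read in the expression clusters, which were drawn without peaks. HMGA2 in cluster 3, CLDN11 in cluster 4 and SAA4 in cluster 6 had no promoter value and were passed over for the next gene. Of the 10 genes with the largest expression ratio among those with a promoter value, the promoter interval lay above 1 for 9 in cluster 5, 5 in cluster 4, 4 each in clusters 3 and 6, 2 each in clusters 7 and 8 and 0 in clusters 1 and 2. In cluster 6, 1 of the 4 was ELF3 (1.33-fold, 1.02 to 1.70), which took the place of SAA4. The interval lay below 1 for PDGFD in cluster 1 (0.752-fold, 0.566 to 0.995) and for no other of these genes. The clusters cannot be ranked by these numbers, since expression ratios and promoter counts differ between them. The largest expression ratio was 1.63-fold in cluster 1 and 1.78-fold in cluster 2. In cluster 5 the promoters of PTPRQ (1.87-fold, 1.46 to 2.35), FHIT (1.67-fold) and ADGRL3 (1.65-fold, 1.38 to 1.97) were more accessible, and that of PPP2R2B stood at 1.00-fold (0.789 to 1.26). The sum for FHIT held 5143 counts in the other cells against 1187 for PTPRQ, and may include peaks away from the promoter. In cluster 4 the promoter of CYP24A1 was 2.68-fold (2.00 to 3.56) and that of CLSTN2 1.82-fold (1.22 to 2.64) more accessible, and that of OSCAR stood at 0.885-fold (0.635 to 1.20). In cluster 6 LCN2 stood at 2.82-fold (1.82 to 4.20) and SAA2 at 2.62-fold (1.28 to 4.88), but CXCL1 at 0.747-fold (0.151 to 2.27) and CXCL8 at 0.955-fold (0.522 to 1.61). In cluster 3 the promoters of IL1RAPL1 (1.07-fold, 0.943 to 1.21) and SAMD3 (1.13-fold, 0.903 to 1.41) had intervals that include 1, as had in cluster 7 those of IGFBP5, INHBA, ADAMTS6 and DUSP4, while KCNN2 stood at 1.44-fold there. In cluster 8 the promoter of OASL stood at 1.88-fold (1.04 to 3.13) and that of IFIT2 at 0.726-fold (0.291 to 1.51). Promoters had few counts there, such as 14 for IFIT2, 5 for CCL5 and 4 for RSAD2, so intervals that include 1 say little. Over the 205 genes at least 2-fold higher in cluster 5 the median log2 promoter ratio was 0.28, against 0.00038 to 0.092 for matched random lists, and over the 242 lower genes it was -0.35. Over the 221 higher genes of cluster 8 it was 0.079, against -0.064 to 0.078.

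Across genes, which are not independent replicates, expression and promoter ratios correlated with r = 0.303 in expression cluster 3, 0.248 in cluster 4, 0.386 in cluster 5, 0.158 in cluster 6, 0.239 in cluster 7 and 0.0417 in cluster 8, and with 0.0559 and 0.0551 in clusters 1 and 2. The chromosome-wide shifts of clusters 3, 4, 5 and 7, given below, move both ratios together. Those chromosomes were not left out, so these correlations and the promoter medians above do not separate such shifts from changes at single promoters. Of 100809 peaks compared, 3954 were at least 2-fold higher and 6166 lower in cluster 5, 3505 and 5922 in cluster 3, 3003 and 2423 in cluster 6, 2974 and 1967 in cluster 7, 2934 and 2664 in cluster 4, and 1364 and 338 in cluster 8. They numbered 190 and 252 in cluster 1 and 127 and 730 in cluster 2. The intervals were not adjusted for the 100809 peaks, and the simulations gave no rate of false calls for single peaks. How many of these peaks counting error alone would give was not determined. The counts may therefore hold many false calls, above all in the small clusters, and do not rank the clusters by their difference in accessibility. In cluster 5 a peak on chromosome 7 (137161070 to 137161964 of GRCh38), 182216 bp from the start of PTN, was 11.7-fold higher (7.25 to 18.8). A peak on chromosome 5 (174724089 to 174724996), 39 bp from the start of the homeobox gene MSX2, was 11.4-fold higher (7.01 to 18.3). At a minimum of 500 counts per peak the peaks past 2-fold in either direction numbered 1375 in cluster 5, 463 in cluster 3 and 0 in clusters 1 and 2.

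Whole chromosomes shifted in the same direction in both modalities, a pattern looked for after the data were seen. In expression cluster 5, chromosome 14 lay at a log2 shift of -0.59 in accessibility (-0.63 to -0.54) and -0.42 in expression (-0.48 to -0.37), chromosome X at -0.39 and -0.40, and chromosome 21 at -0.35 and -0.20. Chromosome 13 lay at 0.35 and 0.29 and chromosome 22 at 0.30 and 0.25. In expression cluster 7, chromosome 22 lay at 0.61 in accessibility (0.56 to 0.64) and 0.52 in expression (0.45 to 0.58), and chromosome 6 at -0.20 and -0.22. In cluster 3, chromosomes 3, 18 and 22 lay at -0.22, -0.31 and -0.20 in accessibility and at -0.16, -0.22 and -0.18 in expression, and in cluster 4 chromosome 13 lay at -0.22 and -0.15. No chromosome was called in expression clusters 1, 2, 6 and 8. Across the 23 chromosomes the shifts of both modalities correlated with r between 0.885 and 0.976 in clusters 3 to 7, and with 0.378, 0.382 and 0.299 in clusters 8, 1 and 2.

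**Figure D4:**
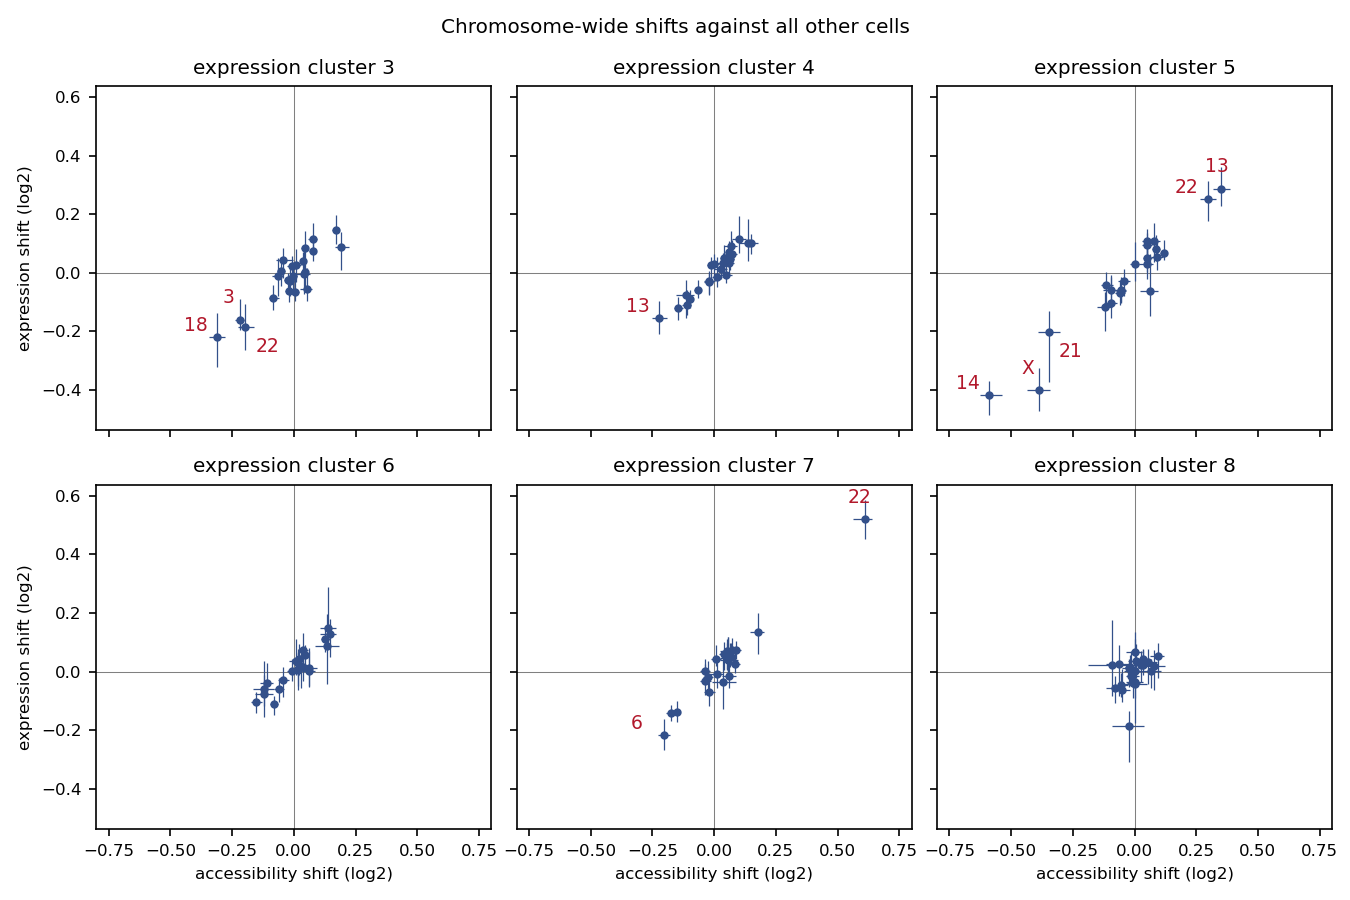
Median log2 shift of each of 23 chromosomes in accessibility (horizontal axis) and expression (vertical axis) in expression clusters 3 to 8 against all other cells, with 95% intervals and with called chromosomes numbered. Chromosome 22 of cluster 7 (0.61 and 0.52) and chromosome 14 of cluster 5 (-0.59 and -0.42) lie farthest from 0.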

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

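Of the tests in this part, the equal-depth test of cluster 1, both tests at matched depth, both tests by chromosome windows, the copy number test and the separate tests of the genes that define cluster 3 and clusters 5 and 7 were written after the results were seen, as was the choice to leave out cells by Scrublet score, and the chromosome shifts themselves were found by exploring the data.

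Barcodes that were not kept as cells held 69.6% of all UMIs, a signal in data that no comparison uses. The barcodes not kept include 412157 empty droplets of up to 100 UMIs with 791461 UMIs in all, which gave the free RNA profile. A further signal outside the main comparisons is the 2217 barcodes with at least 1000 UMIs and 1000 peak counts that were left out for over 20% mitochondrial UMIs. They had a median of 1792 UMIs and 22.9% mitochondrial UMIs. Against the cells kept, 0 of 7400 genes were at least 2-fold higher in them and 1 was lower, RSAD2 (2.14-fold lower).

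Chromatin cluster 1, the largest, had no gene at least 2-fold from the other cells. Low depth was tested first by thinning every cell to 2254 peak counts, after which 14.1% of the cells of clusters 2 to 5 shared a cluster with most of cluster 1, under the 20% set beforehand as evidence against depth. That bound was wrong for this test, because 49.9% of cluster 1 lies below 2254 peak counts and stays shallower than the thinned cells. With those cells left out, a test added after that outcome, 81.5% of clusters 2 to 5 joined most of cluster 1 (67.5%, 98.0%, 73.7% and 99.9% of clusters 2, 3, 4 and 5). At that depth clusters 3 and 5 were no longer separated from each other either, and the shallowest cells of cluster 1 were absent. This test therefore cannot tell low depth from a group of its own. The ratio of cluster 1 also went with that of free RNA, with r = 0.339 across genes, which are not independent replicates, so low depth and free RNA both stay open as sources of this cluster, and no biological explanation was tested.

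MAPK output genes were higher in chromatin cluster 2, with a median log2 ratio of 0.47. Of the compared members DUSP4, ETV5 and SPRED2 met the CPM floor only in that cluster. Over thinned cells the same 9 members had a median of 0.68, which says little about depth, since thinning with the clusters held fixed changes only the weight of each cell. Depth is argued against by a comparison with other cells of the same UMIs and peak counts (1849 cells on each side), where the median was 0.47 (0.38 to 0.56 over 20 draws). Doublets and dissociation stress cannot be told apart: leaving out the 713 cells of highest Scrublet score gave 0.47, but that score marked 0 cells at its own threshold and was no test, and the 4 immediate-early genes compared had a median of 0.19, with JUN at 0.39 and ATF3 at 0.52 but JUNB at -0.27 and IER2 at -0.0028. The median was 0.12 with at most 10% mitochondrial UMIs, where DUSP4 and ETV5 turned to the opposite side, but the cells were clustered again and the matched cluster had a Jaccard overlap of 0.22 with cluster 2, so whether the limit or another group of cells moved it was not tested. A difference in line or treatment may underlie it and was not tested, since no cell could be assigned to either.

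Chromosome-wide shifts were tested in expression clusters 3, 5 and 7, and the call of chromosome 13 in cluster 4 was left out of these tests. Thinning with the clusters held fixed left 96.1% of the summed accessibility shift (89.8% in cluster 3, where chromosome 22 went from -0.19 to -0.14), which says little, since it changes only the weight of each cell. Depth is argued against by a comparison with other cells of the same UMIs and peak counts, where 103% of the shift was left as the median of 20 draws (95.6% to 111% in cluster 3, 98.2% to 107% in cluster 5 and 96.0% to 106% in cluster 7). On the side of the call lay 97.9% of the windows (95 of 97) over 10 pairs of cluster and chromosome, which the same peaks had helped to choose. Chosen by their expression shift alone the pairs were the same 10, so the 97.9% of accessibility windows on the side of that shift argue against a few features per chromosome. A choice of cells by the genes of these chromosomes is argued against in clusters 5 and 7, with 101% left when those genes were kept out of the clustering and all 7 chromosome calls made again. Over the 3 clusters 96.1% was left, past the 80% set beforehand, but that bound was wrong for cluster 3, since clusters 5 and 7 alone gave 78.7% of the summed shift. In cluster 3 this explanation stays open, with 79.1% left and a matched cluster of 998 cells at a Jaccard overlap of 0.471. Its accessibility shifts of chromosomes 3, 18 and 22 were then -0.17 (-0.19 to -0.16), -0.24 (-0.27 to -0.21) and -0.18 (-0.20 to -0.16), but the calls of chromosomes 3 and 22 ended, because their expression shifts went from -0.16 (-0.19 to -0.090) to -0.14 (-0.17 to -0.10) and from -0.18 (-0.26 to -0.11) to -0.14 (-0.19 to -0.061), under the limit of 0.15. Accessibility and expression shifts correlated across 23 chromosomes with r of at least 0.885 in each of the 3 clusters, which is consistent with a difference in copy number between groups of cells. It is a hypothesis found and tested on the same data, and whether such groups follow the lines was not tested.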

How the results depend on the processing

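The unweighted graph, the removal of cells of highest Scrublet score and the rule for matching clusters were chosen after seeing the data, and the other alternatives were planned. Over 22 alternatives, 20 planned and 2 added, 342 results gave 5946 values. Of these, 5231 stayed within their interval or within 1.5 times the count, 669 moved and 46 reversed. The 46 are 26 for genes, 19 for lists and 1 adjusted Rand index. They leave out changes of sign inside a main interval that holds both signs. Counts were judged by their total, so a turned split of higher and lower is left out too. The values under Scrublet's automatic threshold (155 for genes, 161 for lists and 7 counts) are among the 5231 and say nothing about stability, since it removes no cell. No paired analysis was possible because the cells form 1 pooled sample. The totals include named genes in comparisons where they lie under the 20 CPM floor (ANKRD1, DUSP6 and SPRY4, and CCN2 in clusters 4 and 5). Except where a minimum of UMIs or counts changes the features compared, the cause was not tested.

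The main counts of genes at least 2-fold apart are 46 for chromatin cluster 1 against 2, and 0, 102, 74, 108, 205 and 160 for clusters 1 to 6 against all other cells. Those of peaks are 442, 857, 9427, 5598, 10120, 5426, 4941 and 1702 for expression clusters 1 to 8, of which the share due to counting error was not determined. Under another clustering a cluster without a mutual best match gives no value. If every cluster were matched to its best partner, 115 values in place of 44 would be reversed over the settings that change clusters, 83 in place of 23 of them at most 10% mitochondrial UMIs.

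With at least 500 UMIs and 500 peak counts, genes numbered 15 for cluster 1 against 2 and 38, 27, 18 and 45 for clusters 2 to 5. The YAP/TEAD median of cluster 5 was -0.19, peaks of expression cluster 2 numbered 553, correlations of expression and promoters were 0.0174, 0.308, 0.167 and 0.0722 in expression clusters 2, 5, 7 and 8, and the adjusted Rand index was 0.0525. Expression clusters 3 and 4 were not found again.

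With at least 2000 UMIs and 2000 peak counts, genes numbered 114 for cluster 1 against 2 and 3, 2.3e+02, 173, 322 and 345 for clusters 1 to 5. The efflux pump median of cluster 1 against 2 was 0.10. In cluster 4 the MAPK median was 0.29, S phase 0.069 and G2/M phase 0.22, and in cluster 2 INHBA was at -0.16 and CCN1 at -0.17. Peaks numbered 4059, 2208, 4723 and 2831 in expression clusters 3, 4, 5 and 7, correlations were 0.194, 0.325 and 0.202 in expression clusters 4, 5 and 7, and the adjusted Rand index was 0.330. Expression clusters 2 and 8 were not found again.

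At most 10% mitochondrial UMIs reversed the most values, with the cluster matched to chromatin cluster 2 at a Jaccard overlap of 0.22. Clusters 1 and 2 against all other cells are there the same comparison as cluster 1 against 2, mirrored for cluster 2, so values given for more than 1 of them are not separate results, although the totals above count each. Genes numbered 4 for cluster 1 against 2, 4 for cluster 1 and 4 for cluster 2. For cluster 1 against 2 the medians were -0.12 for MAPK output, 0.13 for S phase and -0.031 for cholesterol synthesis, and the log2 ratios were PTPRQ -0.20, PPP2R2B -0.066, DANT2 -0.33, HMGA2 0.095, SAMD3 0.45, DUSP4 0.38, RUNX2 0.26, ETV5 1.21, IFIT3 0.18, CXCL8 -0.42 and CCL20 -0.89. For cluster 2 the medians were 0.12 for MAPK output, -0.13 for S phase and 0.031 for cholesterol synthesis, and the log2 ratios were HMGA2 -0.095, SAMD3 -0.45, PTPRQ 0.20, ADGRL3 0.40, DUSP4 -0.38, ETV5 -1.21, NT5E -0.42 and IFIT3 -0.18. Peaks numbered 239, 239 and 308 in expression clusters 1, 2 and 8, correlations were 0.0242 and 0.0161 in expression clusters 1 and 2, and the adjusted Rand index was -0.0285. Chromatin clusters 3 to 5 and expression clusters 3 to 7 were not found again.

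At Leiden resolution 0.2, genes numbered 71 for cluster 1 against 2, 1 for cluster 1 and 133 for cluster 3, peaks 10107 in expression cluster 1 with a correlation of 0.382, and the adjusted Rand index was 0.0544. Chromatin cluster 5 and expression clusters 2, 3, 4, 6, 7 and 8 were not found again. At resolution 1.0, genes numbered 0 for cluster 1 against 2 and 22, 20, 55 and 336 for clusters 2 to 5. The MAPK median was -0.21 for cluster 1 against 2 and 0.13 for cluster 1, the mesenchymal median of cluster 1 was 0.020, the G2/M median of cluster 4 was 0.027 and AXL in cluster 3 was -0.050. DUSP6 for cluster 1 against 2, under the floor in both clusters, was 0.074, against -0.94 (-1.64 to -0.26) in the main clusters. Peaks numbered 1221 and 1408 in expression clusters 1 and 2, correlations were 0.0197 and 0.223 in expression clusters 2 and 4, and the adjusted Rand index was 0.0681.

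In cluster 4 the S and G2/M medians were 0.0034 and 0.016 with 30 neighbours, 0.033 and 0.0049 with seed 1, 0.019 and 0.019 with 20 components and 0.071 and 0.046 with 50 components. With 30 neighbours the correlations of expression clusters 2 and 4 were 0.0299 and 0.194 and the adjusted Rand index 0.121. With seed 1 they were 0.0306 and 0.180, the index 0.0858 and the genes of cluster 5 numbered 135. With 20 components the genes of cluster 5 numbered 89, correlations of expression clusters 1 and 2 were 0.0132 and 0.0163 and the index 0.132. With 50 components genes numbered 1 and 163 in clusters 1 and 4, peaks 719 in expression cluster 1, correlations of expression clusters 1, 3 and 4 were 0.120, 0.246 and 0.218 and the index 0.121. Expression clusters 6 and 8 were not found again with 50 components. Over seeds 1 to 9 the adjusted Rand index with the main chromatin clusters lay between 0.790 and 0.871 and with the main expression clusters between 0.787 and 0.936.

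With clusters drawn from expression without the list genes, genes numbered 188 for cluster 1 against 2 and 2, 217, 195, 493 and 521 for clusters 1 to 5. In cluster 1 the YAP/TEAD median was 0.044 and that of other receptor tyrosine kinases 0.065, and the MAPK median of cluster 3 was -0.69. CCN1 was at 0.10 for cluster 1 against 2, and in cluster 2 INHBA was at -0.83 and CCN1 at -0.22. The adjusted Rand index was 0.0894. In the graph without weights, added later, genes numbered 14 and 523 in clusters 4 and 5 and correlations were 0.0835, 0.0241 and 0.212 in expression clusters 1, 2 and 4, and expression clusters 7 and 8 were not found again.

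A minimum of 10 UMIs, which admits genes with few counts, gave 348 genes for cluster 1 against 2 and 143, 546, 412, 525 and 640 for clusters 1 to 5. A minimum of 500 UMIs, which leaves such genes out, gave 16 for cluster 1 against 2 and 61, 39, 64, 108 and 72 for clusters 2 to 6. Peaks with at least 500 counts numbered 0, 0, 463, 374, 1375, 761, 704 and 554 in expression clusters 1 to 8. The mean over thinned cells gave 1 gene in cluster 1 and a mesenchymal median of 0.0053 there, and leaving out cells of highest Scrublet score, added later, gave 1 gene in cluster 1 and says nothing about doublets, since the score marked 0 cells.

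No value counts as reversed under TMM scaling, median-of-ratios scaling or scaling by counts in promoter peaks. The same holds for list members with at least 10 UMIs and for the mean in place of the median. The splits of genes higher and lower in chromatin clusters 2, 3 and 5 did turn under TMM and median-of-ratios scaling. TMM and median-of-ratios scaling moved the median over genes by at most 0.091. Over the alternatives that gave a value, the YAP/TEAD median lay between 0.18 and 0.38 in cluster 3, -0.37 and -0.15 in cluster 4, and -0.50 and -0.19 in cluster 5, and the MAPK median between 0.12 and 0.69 in cluster 2 and between -0.57 and -0.31 in cluster 5. Chromatin cluster 6 was not found again with at least 500 or at least 2000 UMIs and peak counts, at most 10% mitochondrial UMIs, clusters drawn from expression without the list genes or the graph without weights. In the other alternatives none of its values counts as reversed. Its YAP/TEAD and MAPK medians, whose main intervals include 0, did change sign there, down to -0.038 and -0.027. Not run were the hashtag rule, each channel alone, motif shares, the difference in drug response and the alternatives that need replicates.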

Other observations

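The YAP/TEAD and MAPK test in this part was planned, and the chromosome shifts of chromatin clusters were looked for after the data were seen.

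Single peaks marked the other expression clusters too. A peak on chromosome 14 (72883754 to 72884655), 8444 bp from the start of DPF3, was 5.34-fold higher in cluster 3 (3.65 to 7.72), a peak on chromosome 17 (13538840 to 13539684), 16781 bp from the start of HS3ST3A1, 6.33-fold in cluster 4, a peak on chromosome 3 (17844678 to 17845511), 438375 bp from the start of TBC1D5, 6.79-fold in cluster 6, and a peak on chromosome 8 (38833703 to 38834620), 67073 bp from the start of PLEKHA2, 9.88-fold in cluster 7 (5.30 to 17.8). In cluster 5 a peak on chromosome 5 (173454977 to 173455871), 125921 bp from the start of STC2, had 2 counts against 678, a ratio of 0.0398 (0.00101 to 0.223).

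Chromosome shifts were also called in chromatin clusters, whose cells were grouped without expression. In chromatin cluster 4, chromosome 14 lay at -0.34 in accessibility and -0.23 in expression, chromosome 13 at 0.23 and 0.21 and chromosome X at -0.22 and -0.21, the directions seen in expression cluster 5. In chromatin cluster 2, chromosome 18 lay at -0.17 and -0.18. These are not separate results from those of the expression clusters. Chromatin cluster 4 held 350 of the 395 cells of expression cluster 5, and chromatin cluster 2 held 533 of the 633 cells of expression cluster 3. The peaks that give the accessibility shifts had also defined the chromatin clusters. The accessibility profiles of expression clusters 4 and 6 over 23 chromosomes correlated with r = 0.924 and their expression profiles with r = 0.881, and those of clusters 3 and 8 with 0.681 and 0.684, the highest among expression clusters 3 to 8. The other pairs lay between -0.567 and 0.179 in accessibility and between -0.621 and 0.237 in expression. Each cluster was set against all other cells, so these profiles share cells, and the value expected without any likeness was not determined. The correlations are across chromosomes, which are not independent replicates.

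The hypothesis that YAP/TEAD target and MAPK output genes vary together from cell to cell, as shared regulation would have it, was tested against 1000 pairs of matched random lists. The rank correlation of 0.017 lay at the 85.9 percentile, inside the middle of the random pairs, so co-variation beyond that of random lists was not found at this depth. The test covers all cells of 1 pool and says nothing about differences between lines or treatments.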
